A study of Mus musculus with 6 samples.

How the data were processed

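Macrophages were sorted as live (DAPI-negative) cells positive for CD45, F4/80 and CD64 from pancreatic islets and epididymal white adipose tissue of 12-week-old chow-fed C57BL/6J males. Total RNA was isolated with a micro column kit, and 10 ng of it went into ribosome-depleted, strand-specific libraries made by random priming and template switching for low input. The deposited values are raw counts, whole numbers of reads per gene that the authors had not normalised. The labels name STAR, featureCounts, Subread 1.6.4 and the GRCm38 genome, while the gene annotation and the strand setting are not given in the sources used here. The table held 50600 genes in 6 libraries, 3 per tissue. Replicate numbers 2, 4 and 6 occur in both tissues, with batch labels m2, m4 and m6. The design text calls the samples autologous, so the same number was taken as the same animal. Whether an islet library holds 1 animal or a pool is not given in the sources used here. Correlations, across genes, of deviations from the tissue mean were 0.046, 0.063 and -0.008 for the same numbers 2, 4 and 6 and -0.142 to 0.103 for other numbers, so the counts themselves do not show the pairing.

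Gene identifiers were matched without their version to GENCODE M21, which was found for 50376 of them (99.56%), for coordinates, gene types and overlapping exons. All 759 genes of the lists were found by symbol, and 183 entries carry a symbol that occurs more than once. Total counts ranged from 4089980 to 9235591 per library. Mitochondrial ribosomal RNA took 4.72% to 15.2% of counts. Precision is given as exact (Clopper-Pearson) 95% binomial intervals for shares of counts in a single library, and as a floor of 3 counts per library where a tissue had none.

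Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with tissue as the group, library sizes were scaled by TMM, and robust quasi-likelihood fits with tissue as the only term were tested as islet minus fat. Adjusted p values are Benjamini-Hochberg values over the 12152 genes tested, with a threshold of 0.05. CPM values are counts scaled by TMM-adjusted library sizes. Folds are fitted values, except that genes with no counts in a tissue are given as bounds against the floor and genes with 1 to 3 counts in a tissue as ratios with a counting interval. The fit was tested on simulated data with the estimated dispersions, in which 100 genes were changed by each size among 12152 genes. Simulated 2-fold and 4-fold changes were recovered in 3% and 42% of cases, with 3 unchanged genes called, and with the replicate number as a block in 0% and 36%.

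Before the data were examined, 21 functional lists and 16 cell marker lists, the designs and the alternatives listed first were fixed. Lists with at least 5 measured members were tested by camera in limma 3.58.1 with a preset correlation of 0.01, by camera with an estimated correlation and by fry, and adjusted over the functional or the marker lists. With an estimated correlation, camera also falls back on the few residual degrees of freedom, so a higher p need not reflect correlated genes. Named genes were Ptprc, Adgre1 and Fcgr1, and the 8 largest changes in each direction among genes past the threshold with an average log2 CPM of at least 5 and no overlap between tissues. This rule left out markers of other cell types, mitochondrial, haemoglobin and ribosomal protein genes and predicted or clone names. The rule also took the 4 smallest adjusted p values in each direction in the antioxidant list, 2 in each direction in every other functional list, and the 2 members with the highest mean CPM in each marker list. Other gene names were chosen after their values were seen. Some genes that the rule takes are counted in their lists and not reported here by name. Of the named genes, 28 have exons that overlap another gene.

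Shares of counts were compared by an exact two-sided permutation test in scipy 1.17.1, whose smallest p for 3 against 3 is 0.1. Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma voom, no filter, a filter of 1 CPM in every library of a tissue, the replicate number as a block, genes of other cell types left out, and each library or number left out. After the data were seen, fits were added without ribosomal RNA genes, without the immediate early and heat shock list, with protein-coding genes alone, and without islet libraries 2 and 4. Ratios between single libraries used a pseudocount of 0.5 CPM. No sample or column was left out of the comparison itself.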

Results

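RNA was sequenced from macrophages sorted from pancreatic islets and from epididymal white adipose tissue, the visceral fat depot beside the testis, of 12-week-old chow-fed C57BL/6J males. The sorted cells were live and carried CD45, a marker of blood-derived cells, and the macrophage surface proteins F4/80 and CD64. There were 3 islet and 3 fat libraries, numbered 2, 4 and 6 in both tissues. Total counts were 5971279, 4089980 and 6923475 in islet libraries 2, 4 and 6, and 9235591, 7450890 and 7649532 in fat libraries 2, 4 and 6. Genes with at least 1 count numbered between 13020 and 15216 in the islet libraries and between 16992 and 19308 in the fat libraries. Fat libraries resembled each other more closely (Pearson correlation of log2 CPM across genes, which are not independent replicates, 0.960 to 0.966) than islet libraries did (0.841 to 0.904), and across tissues the values were 0.707 to 0.759. The series title names an antioxidant program of the islet macrophage, so the comparison addresses which genes, antioxidant genes among them, differ between these macrophages.

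The genes of the sorted surface proteins were present in every library. Ptprc, which encodes CD45, stood at 832 ± 188 CPM in islet and 458 ± 47.8 CPM in fat macrophages (SD, n = 3 per tissue), with an edgeR quasi-likelihood adjusted p = 0.0639 after Benjamini-Hochberg adjustment. Adgre1 (F4/80) and Fcgr1 (CD64) had edgeR adjusted p = 0.265 and 0.264. The call for Ptprc depended on the tool, since DESeq2 and limma voom called it higher in islet (adjusted p = 0.0138 and 0.0394). Without islet replicate 6, Ptprc and Adgre1 passed in edgeR too (adjusted p = 0.00475 and 0.0261). Of 15 measured genes of macrophage identity, 3 rose in islet macrophages, 4 fell and 8 did not pass (5 higher and 4 lower when adjusted over the list alone). Cx3cr1, the fractalkine receptor, rose by 4.71 ± 0.41 (log2, SE), and Mertk, a receptor for dying cells, fell by 3.05 ± 0.34. Csf1r, the receptor for the macrophage growth factor, had a log2 difference of -0.06 ± 0.32. Lyz2, a lysozyme gene, fell by 1.33 ± 0.33 but missed the threshold without islet replicate 2 or fat replicate 2, 4 or 6 (edgeR adjusted p = 0.0651, 0.0684, 0.0915 and 0.0832). The number that rose was 1 without islet replicate 2, islet replicate 4 or any 1 fat library and 6 without islet replicate 6, and the number that fell was 2 without islet replicate 2 or any 1 fat library. The number that rose was also 1 with RLE size factors, with upper-quartile factors, without ribosomal RNA genes or with protein-coding genes alone, and 5 in DESeq2. The list as a set gave a camera adjusted p = 0.471.

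Of 12152 genes tested, 1090 were higher and 1271 lower in islet than in fat macrophages (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 988 and 1204 of them by at least 2-fold. Genes named outside the rule given with the methods, such as Slc7a11, Rsad2, Apoe and Lyve1, were chosen after their values were seen. Simulated genes changed by 4-fold were recovered in 42% of cases and by 2-fold in 3%, with far fewer genes changed than were called here. The Benjamini-Hochberg cutoff depends on the share of changed genes, so these rates do not give the recovery in the real comparison. Some of the genes called here differed by less than 2-fold. A gene that did not pass was not shown to be equal between tissues. Counts moved with single libraries: 494 higher and 593 lower without fat replicate 2, 466 and 687 without fat replicate 4, 547 and 774 without fat replicate 6, and 1649 and 2022 without islet replicate 6. Without both islet libraries 2 and 4, which held the most heat shock RNA, they were 2064 and 2916.

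The largest increases outside the marker lists were in Capn3, a calcium-dependent protease, H2-M2, a non-classical MHC class I gene, Itgb8, an integrin subunit that activates latent transforming growth factor beta, the potassium channel gene Kcnj10, Lrrc3, and the heat shock genes Hspa1b, Hspa1a and Hsph1. Capn3 (ENSMUSG00000079110.11, GRCm38 chromosome 2, 120456019 to 120504913) averaged 74.3 ± 51.8 CPM in islet and 0.0315 ± 0.0546 CPM in fat macrophages, a ratio of 1636 with a 95% counting interval of 293 to 64700. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. H2-M2 (chromosome 17, 37480851 to 37483552) was 282-fold higher (log2 8.14 ± 0.51, SE) and Itgb8 (chromosome 12, 119158022 to 119238802) 235-fold higher (log2 7.88 ± 0.74), with edgeR adjusted p = 7.33e-05 and 2.51e-04. The largest decreases were in Retnla, a marker of alternative activation, the lectin genes Cd209g, Cd209b and Cd209d, Gfra2, Chp2, Dnm1 and the eosinophil chemokine gene Ccl24. Retnla (ENSMUSG00000061100.3, chromosome 16, 48842551 to 48844461) averaged 1637 ± 251 CPM in fat macrophages and had no counts in any islet library, at least 2627-fold lower with a floor of 3 counts per library (edgeR adjusted p = 6.38e-05). Ccl24 (chromosome 5, 135569937 to 135573049) was lower by a ratio of 1927, with a 95% counting interval of 533 to 15910. Hspa1a and Hspa1b are near-identical copies, so the split of reads between them is uncertain.

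Antioxidant genes went both ways. Of 47 measured members, 10 rose, 7 fell and 30 did not pass (14 higher and 9 lower when adjusted over the list alone). Those that rose were Fth1, Hmox1, Gsto1, Msrb1, Nfe2l2, Gclm, Gsr, Prdx1, Prdx5 and Slc7a11, which include the ferritin heavy chain, haem oxygenase, the transcription factor NRF2 and the cystine transporter that feeds glutathione synthesis. Fth1 (ENSMUSG00000024661.6, chromosome 19, 9980598 to 9985098) was 6.55-fold higher, at 8163 ± 1653 against 1246 ± 203 CPM, and Hmox1 (ENSMUSG00000005413.8, chromosome 8, 75093621 to 75100589) 5.07-fold higher, at 1985 ± 1139 against 392 ± 27.6 CPM (SD, n = 3; edgeR adjusted p = 0.00111 and 0.0111). With the replicate number as a block 8 rose and 6 fell, and Slc7a11, Prdx5 and Sod3 missed the threshold (edgeR adjusted p = 0.0605, 0.0660 and 0.0551). In limma voom Slc7a11 and Gsr missed it (adjusted p = 0.178 and 0.0505), and in edgeR Prdx5 missed it with RLE size factors, upper-quartile factors or no filter (0.0567, 0.0606 and 0.0729), and without ribosomal RNA genes, with protein-coding genes alone or without islet libraries 2 and 4 (0.0546, 0.0562 and 0.0962). Those that fell were Mgst1, Selenop, Gpx3, Sesn1, Sod3, Gstm1 and Blvra, among them secreted selenoprotein P and extracellular glutathione peroxidase and superoxide dismutase. In fat libraries 2, 4 and 6, where adipocyte markers took 0.0199%, 0.0227% and 0.00841% of counts, Mgst1 stood at 19.2, 29.7 and 14.8 CPM, Gpx3 at 32.2, 46.7 and 24.0 CPM and Sod3 at 3.40, 5.71 and 2.00 CPM, in the same order. Selenop (6345, 9603 and 6792 CPM) and Sesn1 (80.9, 74.4 and 92.6 CPM) did not follow that order. An order of only 3 libraries can match without a shared source, and an adipocyte source was not tested. Mgst1 was 24.3-fold lower (log2 -4.60 ± 0.58, SE) and Selenop 7.12-fold lower (log2 -2.83 ± 0.49), with edgeR adjusted p = 0.00106 and 0.00483. The intracellular enzyme genes Sod1, Sod2 and Cat did not pass (edgeR adjusted p = 0.256, 0.179 and 0.279). No shift of the list as a set was detected (camera adjusted p = 0.566, and adjusted p = 0.854 with an estimated correlation), and its median log2 difference was 0.36. Fry's test for changes in either direction gave an unadjusted p = 0.0018. Read counts of Fth1 can include those of its processed copies.

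The antioxidant genes that rose differed widely between islet libraries. Slc7a11 stood at 111, 3.73 and 387 CPM in islet libraries 2, 4 and 6 and at 3.03 to 4.94 CPM in the fat libraries, so islet library 4 lay within the fat range. Prdx1 stood at 400, 261 and 1342 CPM in the same islet libraries, Gclm at 53.8, 22.1 and 194 CPM, and Gsr at 67.5, 29.2 and 195 CPM. Txnrd1 (80.3 to 1295 CPM in islet, 109 to 171 CPM in fat) and Srxn1 (23.8 to 620 and 35.1 to 58.9 CPM) did not pass (edgeR adjusted p = 0.0975 and 0.0595). Islet libraries 2 and 4 also held far more heat shock RNA than library 6, with 7.61% (exact 95% binomial interval 7.59 to 7.63), 9.15% (9.12 to 9.17) and 0.571% (0.565 to 0.577) of counts from the 7 heat shock genes that rose. Of the 10 that rose, only Fth1 and Gsto1 passed without each of the 6 libraries, and the number was 2, 2 and 3 without fat replicates 2, 4 and 6. Estimates moved little there, with log2 differences of 2.27, 2.31 and 2.34 for Hmox1 (2.34 with all libraries). For Slc7a11 they were 5.19, 5.32 and 5.55 (5.38 with all libraries). Without islet replicate 6 all 10 passed and 12 members rose, but some differences shrank, Gclm from 2.73 to 1.48 and Prdx1 from 2.37 to 1.35. Hmox1 missed the threshold without fat replicate 2, 4 or 6 (edgeR adjusted p = 0.0687, 0.0610 and 0.0589), as did Slc7a11 (0.0919, 0.0846 and 0.0759), and Msrb1 missed it without fat replicate 2 or 4 (0.0633 and 0.0574). Gclm, Gsr, Nfe2l2, Prdx1 and Prdx5 had edgeR adjusted p between 0.0744 and 0.221 without 1 fat library. Without islet replicate 2, Gsr, Nfe2l2 and Prdx5 had 0.0556, 0.0867 and 0.0714, and without islet replicate 4 Prdx5 had 0.0846. Of the genes that fell, 4 passed without fat replicate 2 or 4. Blvra had edgeR adjusted p = 0.0776, 0.0706 and 0.0518 without fat replicates 2, 4 and 6, Gstm1 0.0843, 0.109 and 0.0994, and Sod3 0.0760 and 0.0865 without fat replicates 2 and 4. Gstm1 also missed the threshold without islet replicate 2 or 4 (0.0840 and 0.0556). With islet libraries 2 and 4 both left out, an alternative chosen after the data were seen, 18 rose and 12 fell. There 1 islet library is assumed to vary like the fat libraries, and the list had an upward camera adjusted p = 0.00225 but adjusted p = 0.471 with an estimated correlation.

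**Figure D1:**
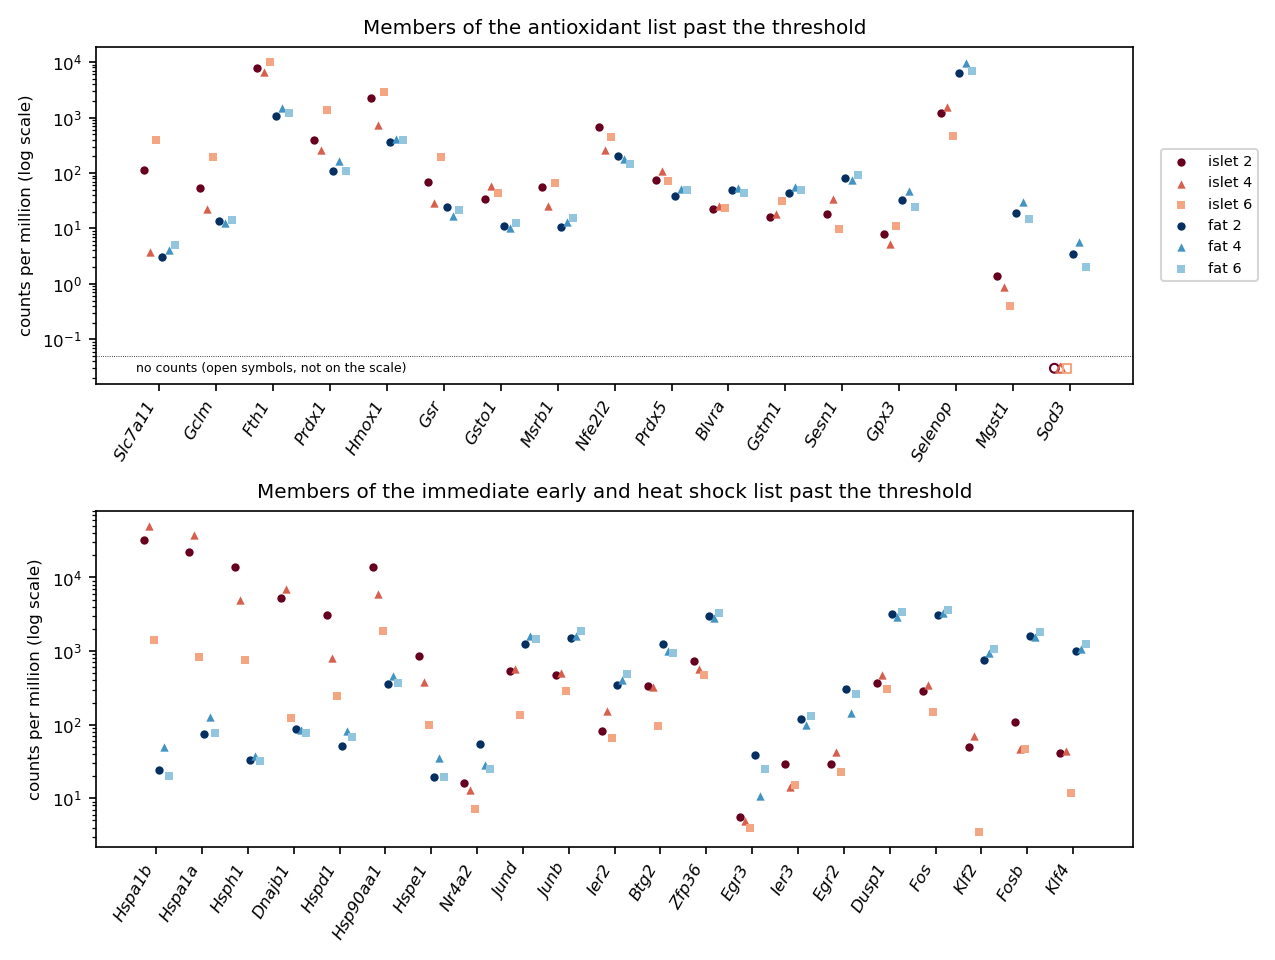
CPM (log scale) in each of the 6 libraries for members past the threshold of the antioxidant list (top) and of the immediate early and heat shock list (bottom), 1 symbol per library, with open symbols below the dotted line for libraries without counts. Slc7a11 ranged from 3.73 to 387 CPM among islet libraries, and Hspa1b from 1406 to 50147 CPM.

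A list written for the supply of NADPH, the reductant of these enzymes, had 16 measured genes. Of these, 4 rose, 2 fell and 10 did not pass (4 and 4 when adjusted over the list alone). Taldo1, Tkt and Pgd of the pentose phosphate pathway rose, and Taldo1 was 5.10-fold higher (log2 2.35 ± 0.31, SE, edgeR adjusted p = 0.00126). Mthfd2 rose 6.92-fold, while Idh1 fell by 2.08 ± 0.41 and Me2 by 1.24 ± 0.32 on the log2 scale. Membership was set from general knowledge, so it does not show which cofactor an enzyme such as that of Mthfd2 or Me2 uses. Of 10 measured genes of oxidant production, Cybb and Hvcn1 rose, Alox5, Alox15 and Xdh fell and 5 did not pass (4 higher and 3 lower when adjusted over the list alone). Cybb, the catalytic subunit of the phagocyte oxidase, was 4.36-fold higher at 2278 ± 496 against 522 ± 44.9 CPM, and Alox5, the first enzyme of leukotriene synthesis, was 217-fold lower (edgeR adjusted p = 0.00187 and 7.49e-05). Hvcn1, a proton channel, was 7.67-fold higher, but 44.2% of its exonic length overlaps Tctn1 on the opposite strand. No set shift was detected for NADPH supply or oxidant production (camera adjusted p = 0.526 and 0.744). Fry's test for changes in either direction gave unadjusted p = 3.51e-05 and 7.17e-07. For oxidant production the median was 0.57 and the mean -0.74 on the log2 scale, with the set test upward, and for NADPH supply the median was 0.27 and the mean -0.002. NADPH genes that rose numbered 2 without fat replicate 2 or 4, and those that fell numbered 1 without any 1 fat library and 4 without islet replicate 6. DESeq2 and limma voom called 4 and 5 NADPH genes lower, and both called 4 genes of oxidant production higher. Without islet libraries 2 and 4, 4 NADPH genes fell and 4 genes of oxidant production rose. Me2 missed the threshold without islet replicate 2 and without fat replicate 2, 4 or 6 (edgeR adjusted p = 0.0742, 0.0639, 0.0685 and 0.135).

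Genes of perivascular and long-lived resident macrophages were lower almost throughout: 23 of 24 measured members fell, 0 rose and 1 did not pass in edgeR (24 lower when adjusted over the list alone, and 0 higher at an unadjusted p under 0.05, in DESeq2 or in limma voom). Lyve1, Folr2, Cd163, Timd4 and Mrc1, surface markers of these cells, were among them. Cd163, the haemoglobin scavenger receptor (chromosome 6, 124304656 to 124330527), averaged 4.84 ± 5.13 CPM in islet and 2516 ± 110 CPM in fat macrophages (SD, n = 3), 548-fold lower. Fcna, a lectin gene, was 752-fold lower (log2 -9.56 ± 0.45, SE, edgeR adjusted p = 4.52e-05). The median log2 difference was -9.16, and -7.58 with the 5 members that had no islet counts set at their bound. The set test gave a camera adjusted p = 3.13e-69, and adjusted p = 0.0627 with an estimated correlation (0.387 with the replicate number as a block too). The number that fell stayed between 23 and 24 whichever library was left out.

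**Figure D2:**
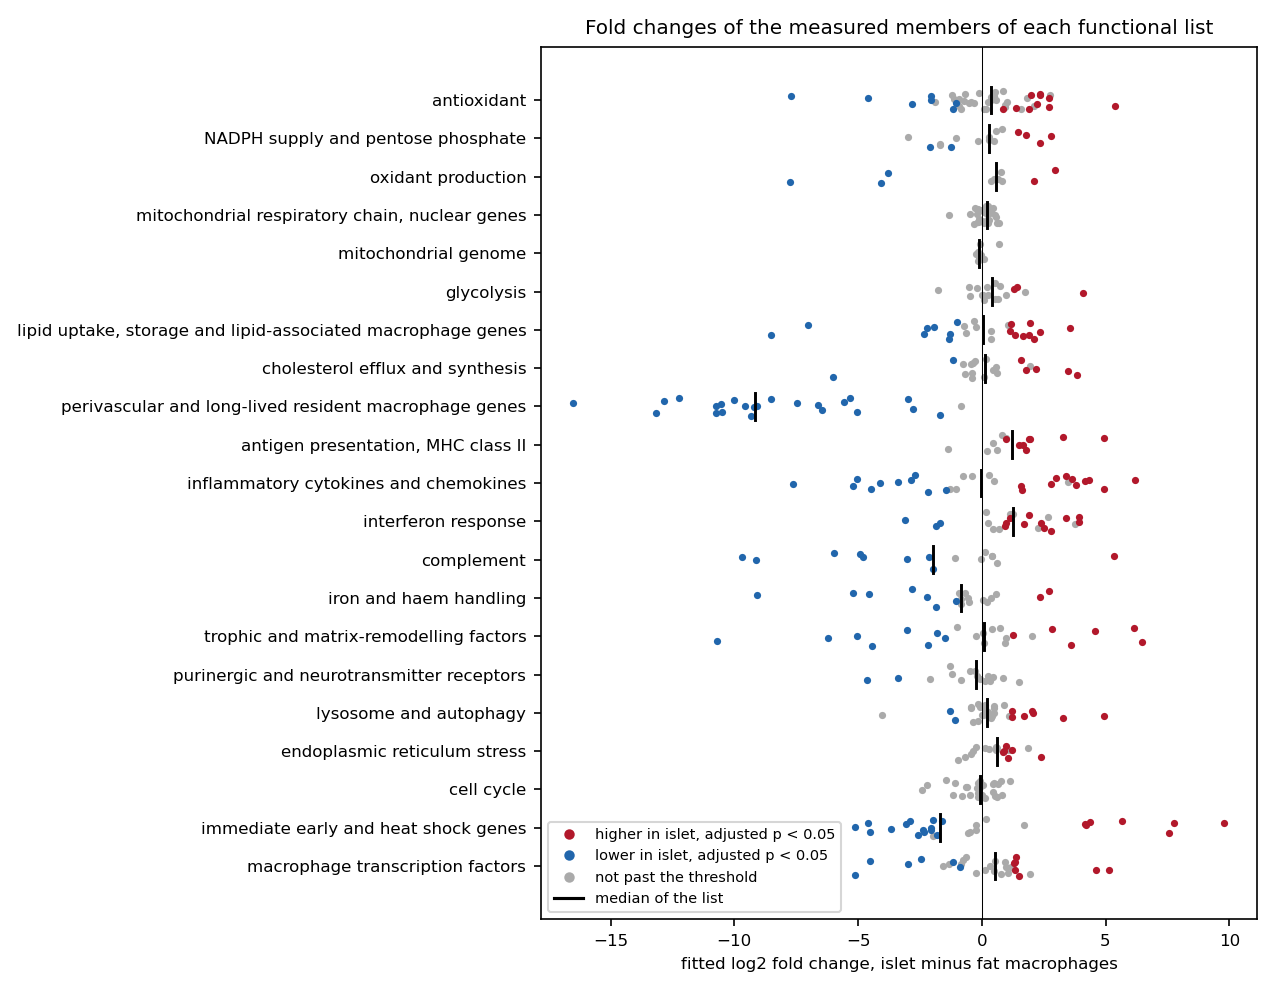
Fitted log2 fold change (islet minus fat macrophages) of every measured member of the 21 functional lists, 1 point per gene, with red and blue for genes past the threshold and a vertical bar at the list's median. The perivascular and resident list lies at a median of -9.16, and fitted values of genes without counts in 1 tissue depend on the prior count.

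Antigen presentation genes of MHC class II were higher: 8 of 14 measured rose, 0 fell and 6 did not pass in edgeR (10 higher when adjusted over the list alone, with 1 lower at an unadjusted p under 0.05 and 0 lower in DESeq2 and limma voom). Ctss, a protease of antigen processing, was 9.70-fold higher (8278 ± 2389 against 853 ± 146 CPM, SD, n = 3), and H2-Ab1 3.72-fold higher (11250 ± 1847 against 3025 ± 147 CPM), with edgeR adjusted p = 7.08e-04 and 0.00453. The set gave a camera adjusted p = 8.96e-05, and adjusted p = 0.333 with an estimated correlation. Interferon response genes followed in part, with 11 of 24 higher, 3 lower and 10 not past (17 and 3 when adjusted over the list alone). Gbp3, a guanylate-binding protein gene, was 5.23-fold higher, while Ifitm3 and Gbp7 fell by 3.10 ± 0.48 and 1.85 ± 0.26 on the log2 scale (SE). Islet library 6 held the highest levels of several members, with Rsad2 at 90.1, 21.8 and 659 CPM and Mx1 at 35.1, 18.9 and 220 CPM in islet libraries 2, 4 and 6. Rsad2 rose, but had an edgeR adjusted p = 0.0891 with the replicate number as a block. Camera gave an adjusted p = 0.00366 for the interferon list, and adjusted p = 0.665 with an estimated correlation. MHC class II genes that rose numbered 4, 4 and 5 and interferon genes 5, 3 and 4 without fat replicates 2, 4 and 6, and 18 interferon genes rose without islet libraries 2 and 4. Members of the Gbp and H2 families share sequence.

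Complement genes were mostly lower. Of 15 measured, 8 fell, 1 rose and 6 did not pass (the same counts when adjusted over the list alone). C4b, the fourth complement component, averaged 1.26 ± 0.86 CPM in islet and 778 ± 166 CPM in fat macrophages, and Cfp, properdin, fell by 5.97 ± 0.57 on the log2 scale (SE, edgeR adjusted p = 2.64e-04). Itgax, the CD11c integrin subunit also carried by this list, rose 40.6-fold, while Itgam, the CD11b subunit, fell by 2.12. C4b shares reads with its near-identical copy C4a. The number of complement genes that rose was 3 without islet libraries 2 and 4. The complement list gave a camera adjusted p = 9.93e-04, and adjusted p = 0.161 with an estimated correlation. Of 19 genes of iron and haem handling, 7 fell, 2 rose and 10 did not pass (8 lower and 2 higher when adjusted over the list alone). Fth1 and Hmox1 rose, and Cp, ceruloplasmin, Tfrc, the transferrin receptor, and Cd163 fell, Cp from 111 ± 17.2 to 3.03 ± 0.18 CPM between fat and islet. That list gave a camera adjusted p = 0.00366, and adjusted p = 0.233 with an estimated correlation. Without fat replicate 2, 4 or 6 the number that rose was 1, since Hmox1 missed the threshold (edgeR adjusted p = 0.0687, 0.0610 and 0.0589), and without islet libraries 2 and 4 it was 5.

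Heat shock genes and immediate early genes, fixed as 1 list, moved apart. Among 28 measured members, 7 rose, 14 fell and 7 did not pass (8 higher and 15 lower when adjusted over the list alone). All 7 that rose encode chaperones: Hspa1a, Hspa1b, Hsph1, Dnajb1, Hsp90aa1, Hspe1 and Hspd1, of which Dnajb1 had an edgeR adjusted p = 0.0556 with the replicate number as a block. Hspa1b (chromosome 17, 34956436 to 34959238) stood at 32627, 50147 and 1406 CPM in islet libraries 2, 4 and 6 and at 24.2, 49.8 and 20.2 CPM in the fat libraries (edgeR adjusted p = 0.00186). The 7 genes took 5.78% ± 4.57 of all counts in islet and 0.0789% ± 0.00785 in fat macrophages (SD, n = 3 per tissue), a share not tested, since these genes were picked because they rose. All 14 that fell are immediate early or related regulators, among them Fos, Fosb, Junb, Egr2, Dusp1 and Klf4. Fosb was 24.2-fold lower (68.0 ± 36.6 against 1646 ± 135 CPM) and Dusp1, a kinase phosphatase, 8.37-fold lower, with edgeR adjusted p = 2.78e-04 and 4.06e-04. The list's median was -1.70 and its mean 0.05 on the log2 scale, and camera gave a downward adjusted p = 0.00590 (adjusted p = 0.844 with an estimated correlation), which became 0.747 without islet replicate 6. Tissue and the isolation of cells from it go together in this design. A part of isolation in these or other differences between tissues was not tested and cannot be told apart.

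Endoplasmic reticulum stress and lysosomal genes rose in part. Of 18 genes of endoplasmic reticulum stress, 6 rose, 0 fell and 12 did not pass in edgeR (6 when adjusted over the list alone, with 1 lower at an unadjusted p under 0.05, 1 in DESeq2 and 0 in limma voom). Hspa5, the chaperone BiP, stood at 8897, 4512 and 1393 CPM in islet libraries 2, 4 and 6 against 867 to 1016 CPM in fat. Endocrine markers (0.899%, 0.627% and 0.454% of counts in these islet libraries) stood in the same order, while Calr (1513, 1276 and 1814 CPM) and Edem1 (202, 207 and 195 CPM) did not follow it. Calr and Edem1 were 2.31-fold and 1.95-fold higher (edgeR adjusted p = 0.0185 and 0.0141). Calr missed the threshold without islet replicate 2 or fat replicate 2, 4 or 6 (edgeR adjusted p = 0.0533, 0.125, 0.0961 and 0.0772), and Edem1 without fat replicate 2, 4 or 6 (0.0941, 0.114 and 0.0635). The number that rose in edgeR was 0 without fat replicate 2, 4 or 6, 1 without islet replicate 2, where 1 fell, and 3 with the replicate number as a block. With islet libraries 2 and 4 left out, 4 rose and 5 fell. Of 31 lysosomal and autophagy genes, 7 rose, 2 fell and 22 did not pass (7 and 3 when adjusted over the list alone). Ctss, the protease also counted with antigen presentation, was 9.70-fold higher, while Ctsl and Grn fell by 1.29 ± 0.25 and 1.07 ± 0.30 on the log2 scale. About 26.8% of the exonic length of Ctsl overlaps another gene on the opposite strand. Lysosomal genes that rose numbered 4 without islet replicate 2 and 3, 3 and 4 without fat replicates 2, 4 and 6, and 1 fell without islet replicate 4 or any 1 fat library and 4 without islet libraries 2 and 4. Grn missed the threshold without fat replicate 2, 4 or 6 and without islet replicate 2 or 4 (edgeR adjusted p = 0.0918, 0.0909, 0.144, 0.116 and 0.0652). The camera adjusted p was 0.0919 for endoplasmic reticulum stress, with 0.0377 without fat replicate 6, 0.0269 without islet replicate 4 and 0.0219 without islet replicate 6, and adjusted p = 0.695 with an estimated correlation. It was 0.0617 for lysosomal genes, with 0.0334 without fat replicate 6, 0.0115 without islet replicate 4, 0.0299 without islet replicate 6 and 0.00382 without islet libraries 2 and 4 (adjusted p = 0.556 with an estimated correlation), and adjusted p = 0.665 with an estimated correlation and all libraries.

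Cytokine and chemokine genes split almost evenly, with 11 of 28 higher, 10 lower and 7 not past (12 and 11 when adjusted over the list alone). Il1a, Il1b, Tnf, Ccl3, Ccl4, Ccl5, Cxcl10 and Cxcl16 rose, and Ccl2, Ccl7, Ccl8, Ccl12, Il6 and Cxcl1 fell. Ccl4 was 20.4-fold higher (305 ± 126 against 14.9 ± 2.57 CPM, SD, n = 3) and Il1a 18.1-fold higher (124 ± 40.5 against 6.79 ± 2.72 CPM). Ccl2, a monocyte chemokine, was 33.1-fold lower (log2 -5.05 ± 0.28, SE), and Ccl7 37.4-fold lower, with edgeR adjusted p = 4.83e-05 and 2.35e-04. Ccl2, Ccl7 and Ccl12 are related in sequence. Of 23 trophic and matrix-remodelling genes, 6 rose, 8 fell and 9 did not pass (7 and 8 when adjusted over the list alone). Mmp12, a macrophage elastase, rose 89.7-fold and Pdgfb, a growth factor, 12.2-fold, with Mmp13, Mmp14, Pdgfa and Hgf also higher (Hgf edgeR adjusted p = 0.0605 with the replicate number as a block). Mmp9, a gelatinase, was lower by a ratio of 1908 (95% counting interval 528 to 15760) and Igf1 33.4-fold lower (12.6 ± 9.25 against 431 ± 15.4 CPM). The camera adjusted p was 0.566 for cytokines and 0.744 for trophic factors. For cytokines the median was -0.04 and the mean 0.04, and for trophic factors the median was 0.11 and the mean -0.27, with downward set tests. Cytokine genes that rose numbered 7 without islet replicate 2, fat replicate 4 or fat replicate 6, and trophic genes that fell numbered 5 without fat replicate 4.

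Lipid genes also split, with 9 of 24 higher, 8 lower and 7 not past (9 and 9 when adjusted over the list alone). Apoe, at 28450 ± 4808 against 7328 ± 1512 CPM, Trem2, Cd9, Lgals3, Lipa and Pparg rose. Cd36, Lpl, Msr1, Fabp4 and Atp6v0d2 fell, Cd36 by 1.93 ± 0.32 on the log2 scale. Cd9 was 5.06-fold and Acsl1 3.73-fold higher (edgeR adjusted p = 6.94e-04 and 0.00176). Of 20 cholesterol genes, 5 rose, 2 fell and 13 did not pass (5 and 2 when adjusted over the list alone). Abcg1, a cholesterol exporter, was 11.1-fold and Ch25h, cholesterol 25-hydroxylase, 14.3-fold higher, while Scd1 was 63.8-fold lower. Fabp4, which is also an endothelial marker, stood at 192, 140 and 32.8 CPM and Scd1 at 164, 204 and 40.7 CPM in fat libraries 2, 4 and 6, where adipocyte markers took 0.0199%, 0.0227% and 0.00841% of counts. The camera adjusted p was 0.952 for lipid genes, whose median was 0.05 and mean -0.36, and 0.166 for cholesterol genes, which was 0.0443 without islet libraries 2 and 4 (adjusted p = 0.395 with an estimated correlation). Lipid genes that rose numbered 2 and 4 without fat replicates 2 and 4, and those that fell 5 without any 1 fat library. Insig1 fell by 1.17 ± 0.35 but missed the threshold without islet replicate 4 and without fat replicate 2, 4 or 6 (edgeR adjusted p = 0.0832, 0.134, 0.132 and 0.117), which left 1 lower cholesterol gene in each. Of 18 glycolysis genes, Slc2a1, the glucose transporter GLUT1, Pkm and Aldoa rose, 0 fell and 15 did not pass in edgeR (3 when adjusted over the list alone, with 1 lower at an unadjusted p under 0.05, 1 in DESeq2 and 0 in limma voom). Slc2a1 was 16.8-fold higher (65.2 ± 37.7 against 3.87 ± 1.33 CPM), and the number that rose was 1 without any 1 fat library and 5 without islet replicate 6, where 3 fell, while 1 fell without islet replicate 4, and 5 rose with no filter. Without islet libraries 2 and 4, 7 glycolysis genes rose and 2 fell. Pkm missed the threshold without fat replicate 2, 4 or 6 (edgeR adjusted p = 0.121, 0.119 and 0.0572). The glycolysis list gave a camera adjusted p = 0.144, which was 0.0328 without islet replicate 2 and 0.00382 without islet libraries 2 and 4, and adjusted p = 0.812 with an estimated correlation (0.556 without islet libraries 2 and 4).

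Nuclear genes of the mitochondrial respiratory chain (31 measured) and genes of the mitochondrial genome (8 measured) gave 0 calls in edgeR. At an unadjusted p under 0.05 there were 1 higher and 1 lower nuclear gene and 0 mitochondrial ones. DESeq2 called 1 nuclear gene higher and limma voom 0, while 3 nuclear genes and 1 mitochondrial gene were called higher without islet replicate 6. Without islet libraries 2 and 4 the calls went the other way, with 3 nuclear genes and 1 mitochondrial gene lower and 0 higher in edgeR. Cell cycle genes (27 measured) also gave 0 calls in edgeR, with 2 lower at an unadjusted p under 0.05, 1 lower in DESeq2 and in limma voom, 1 lower without any 1 islet library, 2 higher without islet replicate 6 and 4 lower without islet libraries 2 and 4. For these lists the counts adjusted over the list alone were 0, and the camera adjusted p values were 0.526, 0.980 and 0.744. Of 16 purinergic and neurotransmitter genes, Maoa, monoamine oxidase A, and Gabbr1, a GABA receptor subunit, fell and 14 did not pass (2 lower when adjusted over the list alone). None rose in edgeR or limma voom, 1 was higher at an unadjusted p under 0.05 and 1 in DESeq2, and 3 and 2 rose without islet replicates 4 and 6, where 3 and 4 fell, beside a camera adjusted p = 0.166. In limma voom 4 fell, and with no filter 2 rose and 4 fell. Without islet libraries 2 and 4, 3 rose and 8 fell, with a camera adjusted p = 0.0390 (adjusted p = 0.395 with an estimated correlation).

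Among 30 macrophage transcription factor genes, 7 rose, 6 fell and 17 did not pass (11 and 9 when adjusted over the list alone). Runx3 was 35.6-fold higher (301 ± 59.9 against 8.48 ± 3.02 CPM, SD, n = 3) and Bhlhe41 24.2-fold higher, with Irf8, Cebpa, Pparg, Id2 and Nfe2l2 also higher. Klf4 was 34.5-fold lower (32.3 ± 17.7 against 1108 ± 139 CPM) and Irf4 5.47-fold lower, with Klf2, Maf, Rxra and Ahr also lower (edgeR adjusted p = 4.06e-04 for Klf4 and 6.19e-04 for Irf4). Rxra had an edgeR adjusted p = 0.0622 with the replicate number as a block. The list gave a camera adjusted p = 0.403. The number that rose was 4 without islet replicate 2, 11 without islet replicate 4, and 2, 3 and 4 without fat replicates 2, 4 and 6, 10 fell without islet replicate 6, and 12 rose without islet libraries 2 and 4.

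RNA of other cell types was measurable in both tissues. Markers of islet endocrine cells took 0.899% (exact 95% binomial interval 0.891 to 0.907), 0.627% (0.619 to 0.634) and 0.454% (0.449 to 0.459) of counts in islet libraries 2, 4 and 6, a mean of 0.660% ± 0.225, against 0.0267% ± 0.00285 in fat (SD, n = 3 per tissue, exact two-sided permutation p = 0.1, the smallest possible). All 11 measured beta cell markers and 17 of 18 markers of other endocrine cells were higher in islet libraries (the same counts when adjusted over the list alone), with Ins2 at 3639 ± 1823 CPM and Gcg at least 1319-fold higher. Reads of Ins1 and Ins2 can be split between these copies. Adipocyte, fibroblast and endothelial markers together took 0.138% ± 0.0670 of counts in fat and 0.0268% ± 0.00376 in islet libraries (exact permutation p = 0.1). Of these, 9 of 10 adipocyte, 11 of 16 fibroblast and 7 of 13 endothelial markers were lower in islet libraries, and 1 fibroblast marker, Dpp4, was higher, with 0 higher in edgeR without islet replicate 2 or any 1 fat library (9, 13 and 11 lower when adjusted over the list alone). Acinar markers had 1 of 2 measured higher, Ctrb1, and duct markers 2 of 3, Krt18 and Epcam, (3 when adjusted over the list alone), of which 1 was called with the replicate number as a block, where Epcam had an edgeR adjusted p = 0.0546, or without any 1 fat library. Endothelial markers that fell numbered 3 without fat replicate 2 and 11 without islet replicate 6, and 4 acinar markers were called higher without islet replicate 2. With no filter 11 acinar and 4 duct markers were called higher and 15 endothelial markers lower, and limma voom called 1 duct marker. Without islet libraries 2 and 4, 3 acinar markers were higher, 1 duct marker and 6 fibroblast markers were lower and 0 fibroblast markers were higher in edgeR. Gnas, counted among the other endocrine markers, missed the threshold without fat replicate 2, 4 or 6 (edgeR adjusted p = 0.0888, 0.0846 and 0.0535). There its log2 difference was 1.23, 1.26 and 1.43, while the median of that list with all libraries was 9.42. In fat, other endocrine markers took 0.0242% of counts and beta cell markers 0.00249%. Whether reads of Gnas came from endocrine cells was not tested.

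Markers of other leukocytes were mixed. Il7r rose and Cd28, Thy1 and Cd2 fell among 5 T and NK cell markers, and 4 of 7 B cell markers fell, among them Igkc. Thy1 had an edgeR adjusted p = 0.107 with the replicate number as a block. Csf3r rose and Mmp9 fell of 2 neutrophil markers, 2 of 9 dendritic cell markers rose (1 without islet replicate 2, any 1 fat library or islet libraries 2 and 4) and 3 fell, and 1 of 8 monocyte markers rose and 4 fell. Fn1, at 13.8 ± 14.1 CPM in islet and 1061 ± 739 CPM in fat, and Ccr2 and Vcan were among the lower monocyte markers. When adjusted over the list alone, 5 monocyte markers and 1 mesothelial marker fell and the other counts were the same. The single mast cell marker measured, 3 red blood cell and 2 mesothelial markers gave 0 calls in edgeR, DESeq2 and limma voom, with 1 mesothelial marker lower at an unadjusted p under 0.05 and 1, 3 and 1 lower without islet replicate 4, islet replicate 6 and fat replicate 6. With no filter 5 mesothelial markers fell, and with a filter of 1 CPM in every library of a tissue or without islet libraries 2 and 4 2. Csf3r missed the threshold without islet replicate 2 or any 1 fat library (edgeR adjusted p = 0.120, 0.113, 0.204 and 0.127). Without fat replicate 4 or 6, 1 T and NK cell marker fell, without any 1 fat library 2 B cell markers, and without fat replicates 2, 4 and 6, 1, 2 and 2 monocyte markers. A B cell marker was called higher without islet replicate 6 or fat replicate 6, in DESeq2 and with no filter, and with protein-coding genes alone 2 B cell markers fell and 0 neutrophil markers rose in edgeR. The set tests gave camera adjusted p = 3.87e-17 for beta cell, 6.28e-33 for other endocrine, 5.18e-08 for adipocyte, 5.02e-07 for fibroblast, 6.16e-06 for endothelial and 0.0216 for B cell markers. With an estimated correlation, other endocrine markers kept an adjusted p = 0.0239 (0.141 with the replicate number as a block), and the others had adjusted p = 0.204, 0.275, 0.275, 0.275 and 0.275. Monocyte markers had a camera adjusted p = 0.0507, which was 0.0155 with the replicate number as a block, but adjusted p = 0.301 with an estimated correlation and 0.290 with both. T and NK cell and dendritic cell markers had 0.223 and 0.928, the latter list with a median of 0.78, a mean of -0.47 and a downward test.

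**Figure D3:**
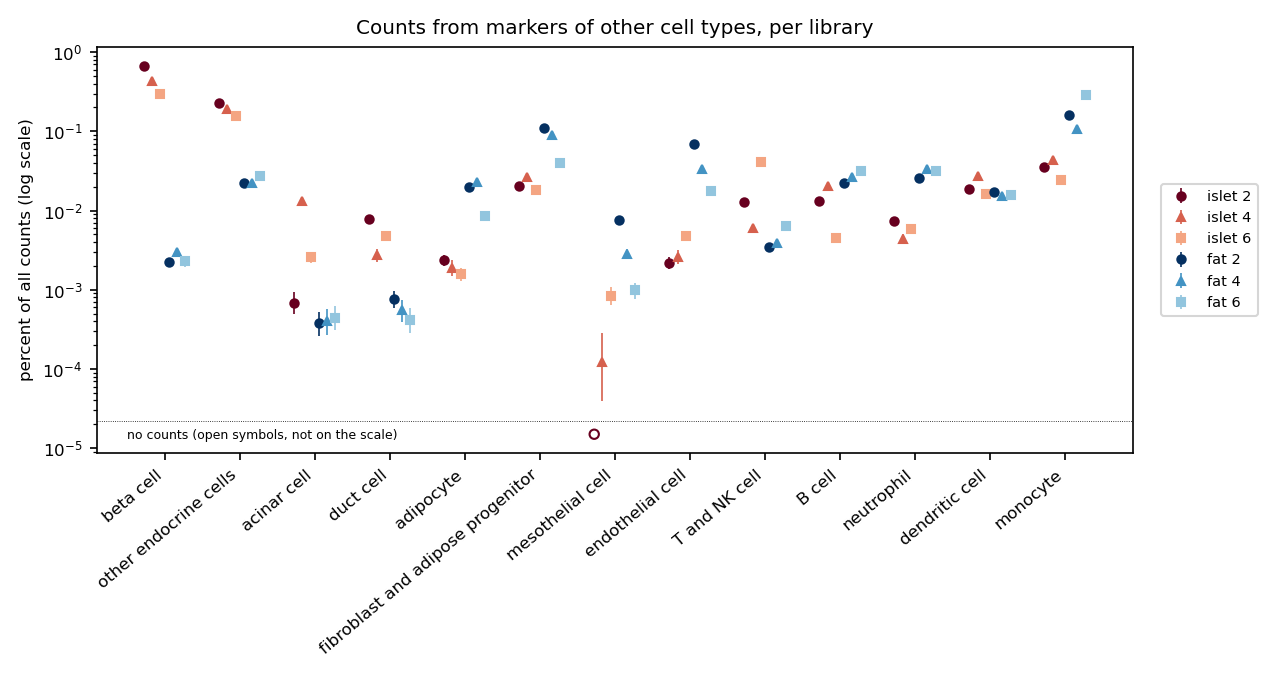
Percent of all counts (log scale) from the markers of each other cell type apart from mast and red blood cells in each of the 6 libraries, with exact 95% binomial intervals as bars and an open symbol below the dotted line for a library without counts. Beta cell and other endocrine markers together lay at 0.454% to 0.899% in islet libraries and at 0.0247% to 0.0300% in fat libraries.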

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

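Without single libraries or both libraries of a number, genes past the threshold ranged from 157 to 1649 higher and from 224 to 2022 lower, and antioxidant genes from 0 to 15 higher and from 1 to 9 lower in edgeR. Normalization, filter, tool and genes left out moved the counts over all genes by under 1.5 times, from 990 to 1486 higher and from 1214 to 1879 lower, and gave 9 to 15 antioxidant genes higher and 7 to 9 lower. Counts of some smaller lists moved more, as given with the results. No gene called in both was called in opposite directions under any alternative. With no filter the median log2 difference of all genes was -0.30, and changes there are relative to that shift. The alternatives without ribosomal RNA genes, without the immediate early and heat shock list, with protein-coding genes alone and without islet libraries 2 and 4 were chosen after seeing the data. Leaving out islet libraries 2 and 4 gave 2064 genes higher and 2916 lower, and 18 and 12 antioxidant genes, with a median of all genes of -0.20. There the lone islet library is assumed to vary like the fat libraries, and the cause was not tested. Of the functional lists, 6 passed camera with the preset correlation and 0 with an estimated correlation, while 6 passed fry. The lists differ: interferon response and the immediate early and heat shock list did not pass fry (adjusted p = 0.139 and 0.178), and lysosomal and purinergic genes did (0.0413 and 0.0208). For complement the estimated correlation was -0.0052, below the preset 0.01, yet camera's unadjusted p rose from 1.42e-04 to 0.0153. Such losses therefore do not show on their own that correlated genes made the result. For the other lists past camera the estimates lay above 0.01. They were 0.603 for immediate early and heat shock, 0.369 for perivascular and resident, 0.256 for interferon, 0.189 for MHC class II and 0.0161 for iron and haem genes. Where the estimate is far above the preset value, a part of correlated genes in the small preset p cannot be excluded. The fit with the replicate number as a block called 884 genes higher and 1103 lower, and 1869 of the 2361 calls were shared. Shared calls numbered 1084, 1145 and 1268 without fat replicates 2, 4 and 6, and 379 without number 2. The block changed no call among the 107 genes named by the rule given with the methods. Much of that rule took the largest changes or smallest adjusted p values, so stable calls among the 107 do not stand for all genes. Genes named outside that rule, such as Slc7a11, Prdx5 and Sod3, did change, with the values given with the results. Of the 107, 91 were past the threshold and 80 of these kept the call without any 1 library. With both libraries of a number left out, more calls were lost: 41 without number 2, 15 without number 4 and 3 without number 6. Without number 6, 4 were gained. Over all alternatives 2154 of 2277 comparisons of a named gene with an alternative kept their side of the threshold, 105 lost it, 18 gained it and 0 reversed.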

Other observations

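The tests on heat shock genes and on endocrine RNA as a source of antioxidant genes were chosen only after the result was seen, and the gene groups described first were noticed in the data. Several genes known from microglia, the macrophages of the brain, were higher in islet macrophages. Tmem119, a microglial surface protein, averaged 126 ± 67.9 CPM in islet and 1.37 ± 0.644 CPM in fat macrophages (SD, n = 3), and Olfml3 196 ± 87.6 against 5.40 ± 1.58 CPM. Fcrls, also a microglial gene, was lower at 36.6 ± 10.1 against 253 ± 53.8 CPM, and P2ry12, which did not pass (edgeR adjusted p = 0.0643, and 0.0433 with the replicate number as a block), stood at 25.2 ± 11.9 against 57.5 ± 9.70 CPM. A list of microglia-associated genes written without those already seen had 12 measured members, of which Slc2a5, Tgfbr1, Cst3, Golm1 and Arhgap5 rose and Bin1 and Ltc4s fell (with the replicate number as a block, edgeR adjusted p = 0.123 for Slc2a5 and 0.0728 for Bin1). It was shifted upward by camera (p = 0.0179), but p = 0.322 with an estimated correlation, p = 0.171 without islet replicate 4 and 0.764 without islet libraries 2 and 4. A partly shared program is a hypothesis that these values may point to and do not settle.

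Pmepa1, a target of transforming growth factor beta, averaged 560 ± 206 CPM in islet and 8.10 ± 2.14 CPM in fat macrophages (SD, n = 3), beside the higher Itgb8 and Runx3. A list written for the response to this factor, without genes already seen, also holds parts of the pathway itself, such as Tgfbr1, Tgfbr2 and Smad3. It had 16 measured members, of which 6 rose, among them Smad7, Skil, Tgfbr1, Itgav and Ldlrad4, and 0 fell in edgeR. Tgfbr1 is also a member of the microglia-associated list, so the set tests of these lists are not independent. Smad7, an inhibitor induced by the pathway, had a log2 difference of 4.32 (adjusted p = 8.81e-05 in edgeR). Camera gave p = 1.46e-04, and p = 0.0968 with an estimated correlation. Stronger signalling by this factor in islet macrophages is a hypothesis that these values do not settle, and measuring phosphorylated SMAD proteins in both macrophages would test it.

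Heat shock genes stood far higher in islet libraries 2 and 4 than in library 6. The median log2 ratio of the 7 risen genes was 4.20 for library 2 over 6, against a median of 1.01 and a 90th percentile of 1.84 for endocrine markers, and 2.73 for library 4 over 6, against 0.468 and 1.08. The lowest ratios among the 7 genes, 2.90 and 1.68, also lay above those percentiles, though the endocrine marker Gcg reached 2.9 and 2.5. This argues against endocrine RNA of fixed make-up as their source. The lowest ratio of the 5 genes other than Hspa1a and Hspa1b, 1.68, argues against reads shared between these 2. A batch or animal effect of similar size in both tissues is argued against too, provided that equal numbers share an animal or batch. Equal numbers carry the same batch label in both tissues, and a shared animal was taken from the word autologous. The counts themselves do not show that pairing. Every islet ratio lay above its fat ratio, with a lowest difference of 1.06. A smaller shared effect cannot be told apart, since Hspa1b reached 1.28 among the fat libraries beside a median of 0.199. Handling of the islet cells, or differences between animals that act in the islet alone, stay open as untested.

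Antioxidant genes that rose varied between islet libraries. Their median log2 ratio was 0.340 for library 6 over 2 and 1.70 for library 6 over 4, against endocrine medians of -1.01 and -0.468 and 90th percentiles of -0.00234 and 0.785. As a set they therefore did not follow most endocrine markers, with 8 and 6 of the 10 above those percentiles. Nfe2l2 and Prdx5 were above neither, and Fth1 and Gsto1 only the first. Single endocrine markers were also higher in library 6, such as Ppy with a log2 ratio of -3.29 for library 2 over 6. Removing the trend with GC content and length left a median log2 ratio of 1.83 for library 6 over 4, so that trend did not account for it. The SE of the mean over the 10 genes was 0.637, which does not measure spread between libraries. Differences between animals or in handling may contribute and were not tested.

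The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 2361 genes and 17 antioxidant genes and the highest other 0 of each, so 1 of the 10 splits reached the real count. Every other split puts both tissues in each group, so the difference between tissues counts there as spread within groups. Few calls were therefore likely in advance. Each group still holds the tissues in unequal numbers, so these splits are not free of a tissue difference for the lists either. For functional lists past camera, 3 of the 10 splits reached the real 6, and the highest other split gave 6. The 3 other splits that part as many pairs of equal number, 3, called 0 genes in edgeR and 4, 4 and 5 lists.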
